A study of Mus musculus with 12 samples.

How the data were processed

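RNA of cultured lymph node dendritic cells was hybridised to 12 Affymetrix mouse 3' expression arrays, 2 for each genotype label (WT or p38a knockout, KO) at 0, 2 and 4 h of Pam3CSK4. The deposited table holds intensity values, 1 linear signal per probe set and array, summarised by MAS5 per the submitters' processing notes; the version, scaling target and detection calls were not given in the sources used here. The RNA was extracted with Trizol and columns and amplified with a 3' in vitro transcription kit, per the labels' protocols. The deposited intensities ran from 0.018 to 12902 and their 2% trimmed means differed 1.79-fold between arrays, so they shared no common scale. Group means of the trimmed means ran from 69.6 (KO 2 h) to 107 (WT 0 h).

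Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation used, 932 had several and 9211 had none, and 64 were array controls. Symbols were matched by Entrez identifier to a RefSeq gene table of the GRCm38.p6 assembly, used for names and gene neighbourhood; 34754 probe sets matched and 0 symbols changed. Only probe sets with 1 symbol were named, giving 18194 genes, 9012 of them with several probe sets, of which the one with the highest mean over all arrays stood for the gene. Genes were kept where that mean reached the 40th percentile of all probe sets (4.73 on the log2 scale, or 10.6 as a signal), which left 12792 tested and 5402 below the filter.

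Tests, lists, alternatives and the naming rule were fixed before the data were examined. That design expected normalized values and took the deposited scale as its main setting, with quantile normalization as an alternative. Because the array summaries showed no common scale, quantile normalization of the linear values became the main setting before any test was run, and the deposited scale became the alternative. Trimmed-mean scaling was added after seeing the data. Values were tested as log2(value + 16), a scale on which fold changes understate those of low genes. Quantile normalization sets every array to one distribution, so changes are relative to the bulk of probe sets.

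One linear model of 6 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with 6 residual and 9.13 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment per comparison and calls at adjusted p under 0.05. Comparisons were 2 h and 4 h against 0 h within each genotype, KO minus WT at each time and averaged over the times, and the differences of the responses. Errors after ± are standard errors unless given as SD. In all, 28 gene lists were tested against other genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. Calls that hold with the estimated correlation are given beside each list. The set of ligand-induced genes was chosen by the mean response over both genotypes, which does not favour either genotype.

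Genes named are Mapk14, all measured cytokines of the TH-polarising list, the 6 highest and 6 lowest called changes per comparison whose arrays do not overlap between the groups, and up to 3 called members of each list with the smallest p. Genes with only clone-like names and antigen receptor segments were passed over in the ranking by size. Genes traced across comparisons were chosen by that rule in at least 1 of them.

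The gene and list tests were tried on log2 values simulated for the 12792 tested genes, so scaling, probe set choice and filter were not tried. Each comparison had 1 simulated data set with 66 or 67 genes per size of change, so the shares are rough and differ between comparisons partly by sampling. For WT 2 h against 0 h the gene test recovered 41.8%, 68.7% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale. For KO minus WT at 2 h it recovered 26.9%, 79.1% and 98.5%, for the difference of responses at 2 h 8.96%, 55.2% and 83.3%, and for the averaged difference 62.7%, 97.0% and 100%. Unchanged genes were called in 0.0715%, 0.0238%, 0.0318% and 0.0476% of cases. Of lists shifted by 0.4 in KO minus WT at 2 h, 7 of 7 were found, and 0 of 12 unshifted lists were called. Genes were simulated as independent of one another, so this does not show how often lists of correlated genes are wrongly called.

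Alternatives were the deposited scale, trimmed-mean scaling, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets without the suffixes _x_at and _s_at, eBayes without trend, and a fit of only the groups compared. Others were the replicate letter as a block, thresholds of 0.1 and of 0.05 with a log2 change of at least 1, an estimated camera correlation, and each array left out in turn. Nothing in the labels says that the 2 arrays of a group came from separate animals or cultures. The same holds for the times of one genotype. The p-values therefore measure the spread between these arrays, which may be technical. The number of arrays limits the precision. No scan date or batch was given in the sources used here, and probe sets with several or no gene symbols were not used here.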

Results

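Messenger RNA was profiled on 12 arrays in lymph node dendritic cells of C57BL/6 mice, the cells that take up antigen and prime T cells. The cells carried a wild-type label (WT) or a p38a-knockout label (KO). p38α, encoded by Mapk14, is a stress- and cytokine-activated protein kinase. The cultures received Pam3CSK4, a synthetic triacylated lipopeptide that activates TLR2, at 1 mg/ml as labelled, an unusually high dose whose unit could not be checked, and were sampled at 0, 2 and 4 h. Each of the 6 combinations of genotype label and time had 2 arrays, named A and B. The series holds no untreated arrays at 2 or 4 h. An effect of the ligand therefore cannot be told apart from one of time in culture. Below, response and ligand-induced refer to change from 0 h in cultures given the ligand. Trimmed means of the deposited signals ran from 66.6 to 119 and array medians from 14.6 to 21.2. Arrays of one group correlated with r between 0.987 and 0.990 across the 12792 tested genes, which are not independent replicates. The highest r of an array with one of another group ran from 0.984 to 0.989, nearly as high. The median SD within a group was 0.145 on the log2 scale. The design asks which genes respond to the TLR2 ligand and which of them depend on p38α in dendritic cells.

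Mapk14, the targeted gene, was read by 6 probe sets, and none of them was lower in the KO arrays at adjusted p below 0.05 in the mean difference over the 3 times. Only 3 of the 6 lay above the expression filter, so the others could hardly show a loss. The brightest gave 8.41 and 8.02 on the WT arrays at 0 h, 7.76 and 7.44 at 2 h and 7.56 and 7.75 at 4 h, in log2(signal + 16). On the KO arrays it gave 8.37 and 8.37 at 0 h, 8.05 and 8.07 at 2 h and 8.04 and 7.93 at 4 h. The KO minus WT difference of this probe set was 0.15 ± 0.13 (SE) at 0 h, 0.46 at 2 h and 0.33 at 4 h, none past the threshold (adjusted p = 0.69, 0.089 and 0.27). Averaged over the times it was higher in KO arrays by 0.31 ± 0.08 (adjusted p = 0.014 among genes and 0.0526 among all probe sets). That call was lost without WT 2 h B (adjusted p up to 0.0521), on the deposited scale, with eBayes without trend and with the mean of all probe sets. Against 0 h Mapk14 was lower by 0.61 at 2 h and by 0.56 at 4 h in WT arrays. The 2 h call was lost without WT 0 h A or WT 2 h B (adjusted p up to 0.062). The 4 h call was lost without WT 0 h A or WT 4 h A (adjusted p up to 0.11) and on the deposited scale. Both were lost with the mean of all probe sets. In KO arrays the changes were -0.31 and -0.39 (adjusted p = 0.12 and 0.055). The position of the deleted part relative to the probe sets was not given in the sources used here, and probe sets outside it cannot check the labels. Genotype directions below therefore refer to the arrays labelled KO and WT.

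**Figure D1:**
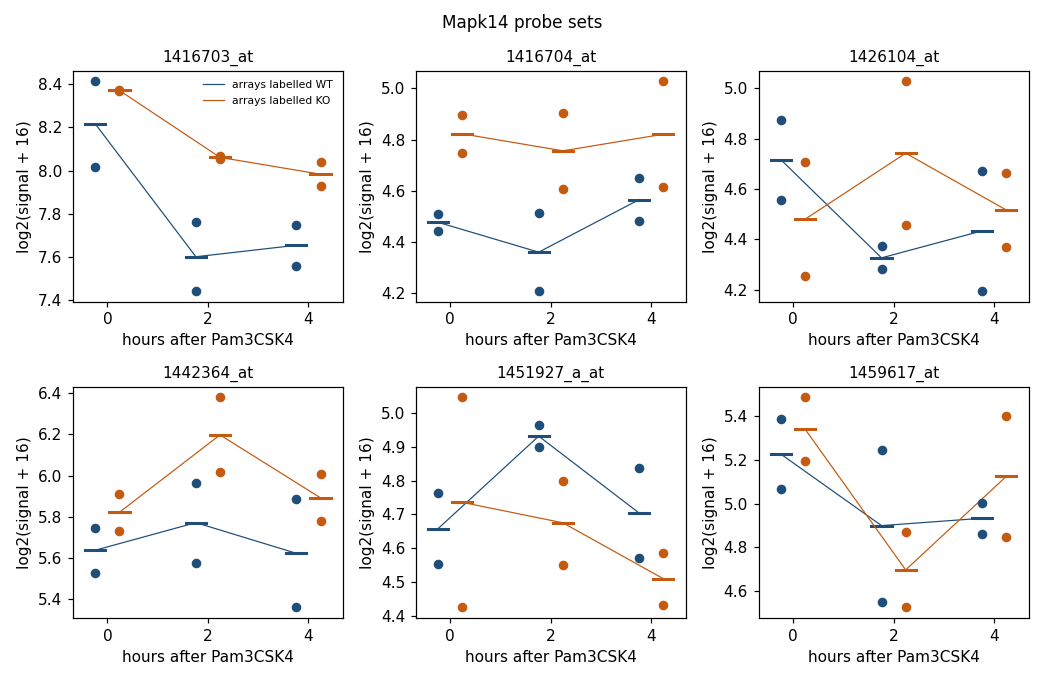
Mapk14 probe sets by time after Pam3CSK4, in log2(signal + 16), one panel per probe set. Points are single arrays, bars are means of 2 arrays, and the brightest probe set had group means from 7.60 to 8.37.

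At 2 h of Pam3CSK4 many inflammatory cytokine, chemokine and co-stimulatory genes of WT dendritic cells stood higher than at 0 h. Tnf rose 12.3-fold (3.62 ± 0.13 (SE), adjusted p = 1.5e-11, log2), and Ebi3, a subunit of IL-27 and IL-35, rose 11.3-fold. Il23a, the p19 subunit of IL-23, rose by 2.07 ± 0.17 (adjusted p = 1.9e-07), and Il12b, the p40 subunit shared by IL-12 and IL-23, by 1.44 ± 0.18. Il6, a cytokine that favours TH17 cells, went from 10.62 ± 0.01 to 11.93 ± 0.06 (SD, n = 2). The highest log2 changes outside the cytokines were those of Dusp14, a dual-specificity phosphatase (4.01), the proliferation marker Mki67 (3.99), the AMP deaminase Ampd3 (3.96), Phlda2 (3.82) and the T cell co-stimulatory ligands Cd70 (3.77) and Tnfsf9 (3.74). The deepest losses were in the transcription factor Nfil3 (-2.38), the chemokine receptor Cxcr4 (-2.25), Map3k14, which encodes the kinase NIK (-2.17), Arhgef10l (-2.10), Flrt3 (-1.99) and Rrad (-1.94). Arhgef10l stood below the filter level at 2 h (4.67), where the size of a change depends on the pseudocount.

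Of 17 measured cytokines of the TH-polarising list, 10 rose and none fell in WT arrays at 2 h (11 higher and 0 lower adjusted over the list alone). The list stood above other genes (camera, adjusted p = 6.4e-12, or 0.0060 with an estimated correlation). Il1a (2.82), Il12a (1.64), Il10 (1.44), Tnfsf4 (0.98) and Il17a (0.69) were among them. For Il12a the size depends on the pseudocount, as its level at 0 h (4.34) lay below the filter. Il1b (-0.14), Il15 (-0.03), Il18 (0.08), Il33 (0.29), Ifnb1 (0.28), Tgfb1 (0.21) and Tgfb2 (0.30) did not pass. NF-kB early targets had 25 of 35 members higher and 1 lower (26 higher and 4 lower adjusted over the list alone), with Cxcl2 (2.41), Tnfaip2 (2.20) and Tnfaip3 (2.01) among the risers. Their adjusted p was 3.7e-19, or 0.0060 with an estimated correlation. Chemokines rose in 17 of 24 cases and fell in 1 (17 higher and 1 lower adjusted over the list alone), led by the CCR4 ligand Ccl17 (2.65), and Ccl3 rose by 2.11. For that list the adjusted p was 3.8e-13, or 0.0060 with an estimated correlation. Co-stimulation and maturation genes rose in 15 of 27 cases and fell in 2 (16 higher and 4 lower adjusted over the list alone), including Cd40 (2.28), with an adjusted p of 9.6e-08 (0.013 with an estimated correlation). Messages with AU-rich elements, which overlap these lists, rose in 23 of 34 cases and fell in 3 (23 higher and 4 lower adjusted over the list alone), among them Ptgs2, the inducible cyclooxygenase (2.46). Their adjusted p was 1.4e-17, or 0.0092 with an estimated correlation.

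Of 32 genes that restrain TLR signalling, 14 were higher and 4 lower at 2 h in WT arrays (14 higher and 7 lower adjusted over the list alone; adjusted p = 5.7e-04, but adjusted p = 0.098 with an estimated correlation), such as Il1r2 (2.38) and Tnip1 (1.17). Toll-like receptors and adaptors gave 11 higher and 2 lower of 29 (11 higher and 2 lower adjusted over the list alone; adjusted p = 0.0040, but adjusted p = 0.13 with an estimated correlation), with Cd14 (1.42) and Tlr2 (1.25). Among 43 p38 and MAPK pathway genes 13 were higher and 5 lower (13 higher and 5 lower adjusted over the list alone; adjusted p = 0.0066, but adjusted p = 0.13 with an estimated correlation), including Spred2 (1.82) and Dusp2 (1.47). AP-1, CREB and immediate-early genes split into 10 higher and 7 lower of 37 (11 higher and 7 lower adjusted over the list alone; adjusted p = 0.018, but adjusted p = 0.084 with an estimated correlation), with Nr4a1 up by 1.24 and Crem at -1.36. The AP-1 list call was also lost on the deposited scale. Lysosome and autophagy genes went down, 10 of 30 lower and 2 higher (2 higher and 11 lower adjusted over the list alone), with Atp6v0d1 (-0.49) and Lamp1 (-0.35) (adjusted p = 0.033, and adjusted p = 0.34 with an estimated correlation). The lysosome call was lost without WT 0 h A or WT 2 h A (adjusted p up to 0.17) and with either other scaling. Macrophage and monocyte markers split, 3 higher and 4 lower of 18, with Vcam1 at 1.30 and Csf1r at -0.65.

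In all, 1079 genes were higher and 1467 lower at 2 h in WT arrays among 12792 tested, of which 236 and 83 changed at least 2-fold. On the deposited scale the split was 269 higher and 2022 lower, with a median shift of all genes of -0.35. There 24 of the 84 called genes that the naming rule took were no longer called.

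At 4 h interferon gamma led the WT response: Ifng rose 27.8-fold (4.80 ± 0.11 (SE), adjusted p = 7.0e-14, log2). Ebi3 (3.81), Ccl17 (3.54) and Cd70 (3.41) were next, with Elobl (3.20) and the G protein subunit Gng4 (3.17). Il6 was up by 1.38 ± 0.06 and Il12a by 2.02. Elobl (4.41) and Il12a (4.34) lay below the filter level at 0 h, so the sizes of their changes depend on the pseudocount. Il23a was up by 0.65 (adjusted p = 0.011), a call lost without WT 0 h B or WT 4 h A (adjusted p up to 0.086) and on the deposited scale. Il17a rose by 1.34 ± 0.15 (adjusted p = 1.1e-05). The lowest changes were Ndrg4 (-2.37), Trim7 (-1.98), Cenpa (-1.78), Myom1 (-1.76) and Dpp4 (-1.71), with Dnah2 (-2.48), an axonemal dynein gene whose other probe set above the filter went the other way.

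The cytokine list again had 10 of 17 members higher and none lower (10 higher and 0 lower adjusted over the list alone), with an adjusted p of 1.3e-09 (0.0071 with an estimated correlation). 24 of 35 NF-kB targets rose and 1 fell (26 higher and 3 lower adjusted over the list alone), for example the C-type lectin Clec4e (1.88), with an adjusted p of 1.1e-16 (0.0071 estimated). Chemokines had 17 of 24 higher and 1 lower (17 higher and 1 lower adjusted over the list alone; adjusted p = 1.0e-13, or 0.0071 with an estimated correlation), including Ccl3 (2.20) and the interferon-responsive Cxcl10 (1.58). Co-stimulation genes had 16 of 27 higher and 2 lower (19 higher and 3 lower adjusted over the list alone; adjusted p = 2.9e-10, or 0.0071 estimated), with Cd40 (2.16) and Cd86 (1.84). AU-rich messages had 22 of 34 higher and 4 lower (22 higher and 5 lower adjusted over the list alone; adjusted p = 1.8e-11, or 0.023 with an estimated correlation). Markers of migratory dendritic cells and Langerhans cells rose, 6 of 18 higher and 1 lower (6 higher and 1 lower adjusted over the list alone), such as Ccl22 (1.07) and Nudt17 (1.16). Their adjusted p was 0.012, and adjusted p = 0.12 with an estimated correlation. Feedback genes gave 15 higher and 7 lower of 32 (16 higher and 7 lower adjusted over the list alone; adjusted p = 0.0089, but adjusted p = 0.19 with an estimated correlation). Receptors and adaptors gave 11 and 3 of 29 (13 higher and 4 lower adjusted over the list alone; adjusted p = 0.013, but adjusted p = 0.21 with an estimated correlation), a call also lost on the deposited scale.

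Lysosome genes were lower in 10 of 30 cases and higher in 2 at 4 h (2 higher and 12 lower adjusted over the list alone), with Lipa at -0.91 and Atp6v0d1 at -0.75. The list had an adjusted p of 0.0089, and adjusted p = 0.28 with an estimated correlation. Laptm5 of that list fell by 0.87, but the probe set without a cross-hybridisation suffix read 0.81 and did not pass. The lysosome call was lost without WT 0 h A (adjusted p up to 0.0527) and with either other scaling. T cell markers went down, 4 of 16 lower and none higher (0 higher and 5 lower adjusted over the list alone), such as Il7r (-0.78), which dendritic cells can also express. The list had adjusted p = 0.037, and adjusted p = 0.15 with an estimated correlation. That call was lost without either WT 0 h array or WT 4 h A (adjusted p up to 0.095) and on the deposited scale. Other single markers moved too, with Csf1r at -1.27, Cd79b at -1.45, H2-Ob at -1.59 and S100a8, a neutrophil and monocyte gene, at 1.66. The totals were 1063 genes higher and 1267 lower, 171 and 94 of them at least 2-fold. The deposited scale gave 251 higher and 581 lower, with a median shift of all genes of -0.16, and 26 of 88 named calls were lost.

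**Figure D2:**
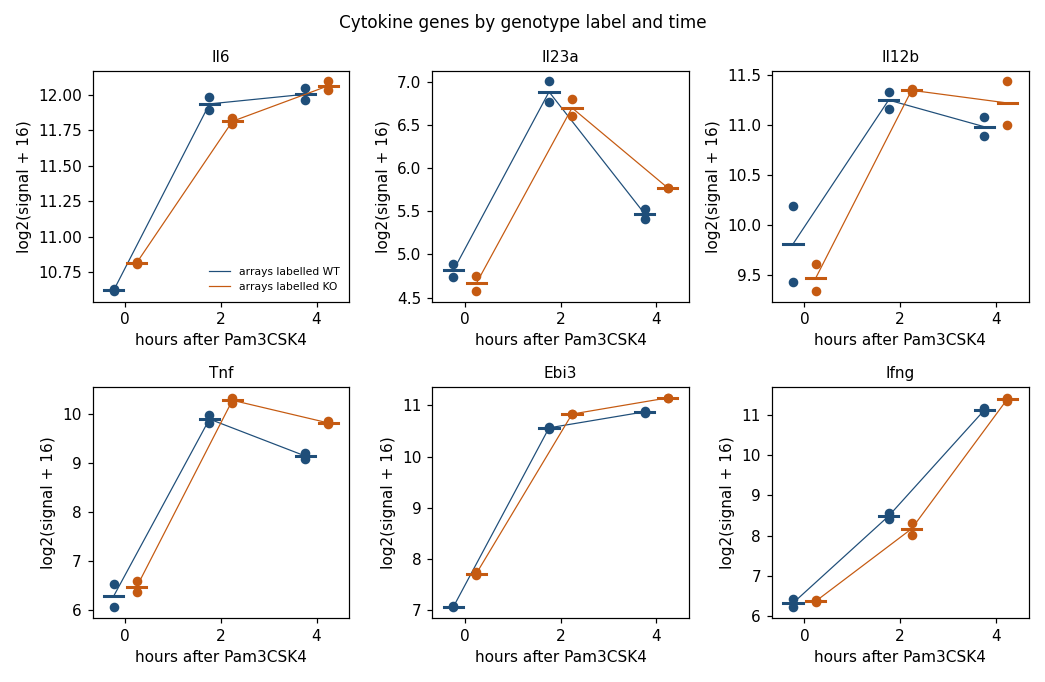
Cytokine genes by time after Pam3CSK4 in log2(signal + 16), with arrays labelled WT in blue and KO in orange. Points are single arrays and bars are means of 2 arrays, and Il6 stood between 11.81 and 12.06 in every stimulated group mean of both genotypes.

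In KO dendritic cells many of the same leading genes changed from 0 h. At 2 h Tnf rose 14.1-fold (3.82 ± 0.13 (SE), adjusted p = 1.1e-11, log2), Dusp14 by 3.76, Mki67 by 3.63, Ampd3 by 3.35, Tnfsf9 by 3.22 and Ebi3 by 3.11. Il6 went from 10.82 ± 0.01 to 11.81 ± 0.03 (SD, n = 2), Il23a rose by 2.03 ± 0.17 and Il12b by 1.88 ± 0.18. The lowest were Nfil3 (-2.49), Flrt3 (-2.39), Map3k14 (-2.32), Gpr65 (-2.19), Dnah2 (-2.10) and Fgfbp3 (-2.02). At 4 h Ifng rose by 5.02 ± 0.11 (adjusted p = 5.3e-14), followed by Ebi3 (3.43), Tnf (3.35) and Ccl17 (3.10). Il1a rose 8.01-fold and Ptgs2 7.02-fold. Il17a rose by 2.23 ± 0.15, Il12b by 1.75, Il12a by 2.18 and Il6 by 1.25. Lowest at 4 h were Dnah2 (-3.06), Ndrg4 (-2.32), Myo18a (-1.87), Trim7 (-1.83), Cxcr4 (-1.70) and Snx24 (-1.69). The changes of Il12a and Il23a started below the filter level in KO arrays (4.36 and 4.66), and their sizes depend on the pseudocount.

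List results in KO arrays are given for 2 and 4 h, in that order. Of the 17 cytokines 11 and 12 rose and none fell, and adjusted over the list alone 11 and 13 rose and 0 and 1 fell (adjusted p = 2.2e-13 and 1.8e-12, or 0.0055 and 0.0052 with an estimated correlation). NF-kB targets rose in 27 and 26 of 35 cases and fell in 2 at each time, and adjusted over the list alone 28 and 27 rose and 3 and 2 fell (adjusted p = 6.0e-23 and 2.9e-21, or 0.0055 and 0.0052 estimated). Chemokines rose in 13 and 16 of 24 cases and fell in 1, with 17 and 16 up and 1 and 2 down adjusted over the list alone (adjusted p = 2.2e-10 and 5.8e-13, or 0.010 and 0.0052 estimated). Co-stimulation genes rose in 14 and 16 of 27 cases and fell in 5 and 3, with 15 and 18 up and 5 and 4 down adjusted over the list alone (adjusted p = 4.6e-07 and 2.9e-10, or 0.016 and 0.0073 estimated). AU-rich messages rose in 24 and 21 of 34 cases and fell in 3 and 5, with 24 and 22 up and 4 and 5 down adjusted over the list alone (adjusted p = 4.4e-17 and 2.6e-11, or 0.010 and 0.024 estimated). AP-1 and immediate-early genes were called only at 2 h, 18 higher and 6 lower of 37 (20 higher and 8 lower adjusted over the list alone; adjusted p = 0.0011, or 0.025 with an estimated correlation), a call lost on the deposited scale. Feedback genes rose in 15 and 16 of 32 cases and fell in 5 (adjusted p = 4.8e-05 and 5.0e-04, but adjusted p = 0.056 and 0.11 with an estimated correlation), with 17 and 16 up and 5 and 6 down adjusted over the list alone. MAPK pathway genes at 2 h gave 13 higher and 2 lower of 43 (13 higher and 2 lower adjusted over the list alone; adjusted p = 0.0016, but adjusted p = 0.094 with an estimated correlation).

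At 4 h type I interferon response genes rose in KO arrays, 10 of 35 higher and 1 lower (11 higher and 3 lower adjusted over the list alone), with Cxcl10 (1.60), Irgm1 (0.67) and Igtp (0.63). Their adjusted p was 0.0012, and adjusted p = 0.42 with an estimated correlation; the WT list at 4 h had 8 higher and 3 lower (adjusted p = 0.28), and the difference between genotypes did not pass (adjusted p = 0.068). Lysosome genes fell in 14 of 30 cases at 4 h (1 higher and 15 lower adjusted over the list alone), with Lipa (-1.21) and Atp6v0d1 (-0.78) (adjusted p = 0.0010, and adjusted p = 0.18 with an estimated correlation). Smaller list calls were made in KO arrays at 4 h. Cholesterol biosynthesis genes were higher in 5 of 20 cases (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.025, but adjusted p = 0.21 with an estimated correlation). Receptors and adaptors gave 10 higher and 3 lower of 29 (11 higher and 3 lower adjusted over the list alone; adjusted p = 0.0088, but adjusted p = 0.18 with an estimated correlation). Neutrophil markers gave 1 higher of 10 (1 higher and 0 lower adjusted over the list alone; adjusted p = 0.037, but adjusted p = 0.17 with an estimated correlation). Stromal and endothelial markers were lower in 5 of 17 cases (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0478, but adjusted p = 0.21 with an estimated correlation). The cholesterol call was lost without KO 0 h A or KO 4 h B (adjusted p up to 0.055), and it and the receptor call were lost on the deposited scale. The neutrophil call was lost without KO 0 h A or KO 4 h A (adjusted p up to 0.095). The stromal call was lost without KO 0 h B, KO 4 h B or either WT 0 h array (adjusted p up to 0.17). At 2 h the lysosome list gave 10 lower and 2 higher of 30 (2 higher and 12 lower adjusted over the list alone; adjusted p = 0.040, but adjusted p = 0.39 with an estimated correlation). The receptor list at 2 h gave 8 higher and 2 lower (9 higher and 3 lower adjusted over the list alone; adjusted p = 0.028, but adjusted p = 0.27 with an estimated correlation). Both calls were lost with either other scaling, the lysosome call without KO 0 h B or KO 2 h A (adjusted p up to 0.15) and the receptor call without KO 0 h B or KO 2 h A (adjusted p up to 0.079).

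Counts in KO arrays were 1004 higher and 1499 lower at 2 h and 926 and 1389 at 4 h, with 207 and 88, and 146 and 112, at least 2-fold. With the deposited values the splits were 195 and 3218 at 2 h and 189 and 664 at 4 h, with median shifts of all genes of -0.41 and -0.20. Without KO 0 h A the 2 h total was 1593 in place of 2503. Of the called genes, 754 rose at 2 h in both genotypes where independent lists would share 84.7, and 943 fell in both where 172 would. At 4 h 716 rose and 879 fell in both, against 76.9 and 138. These comparisons share no arrays. Across all tested genes, which are not independent replicates, the WT and KO changes correlated with r = 0.766 at 2 h and 0.757 at 4 h.

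**Figure D3:**
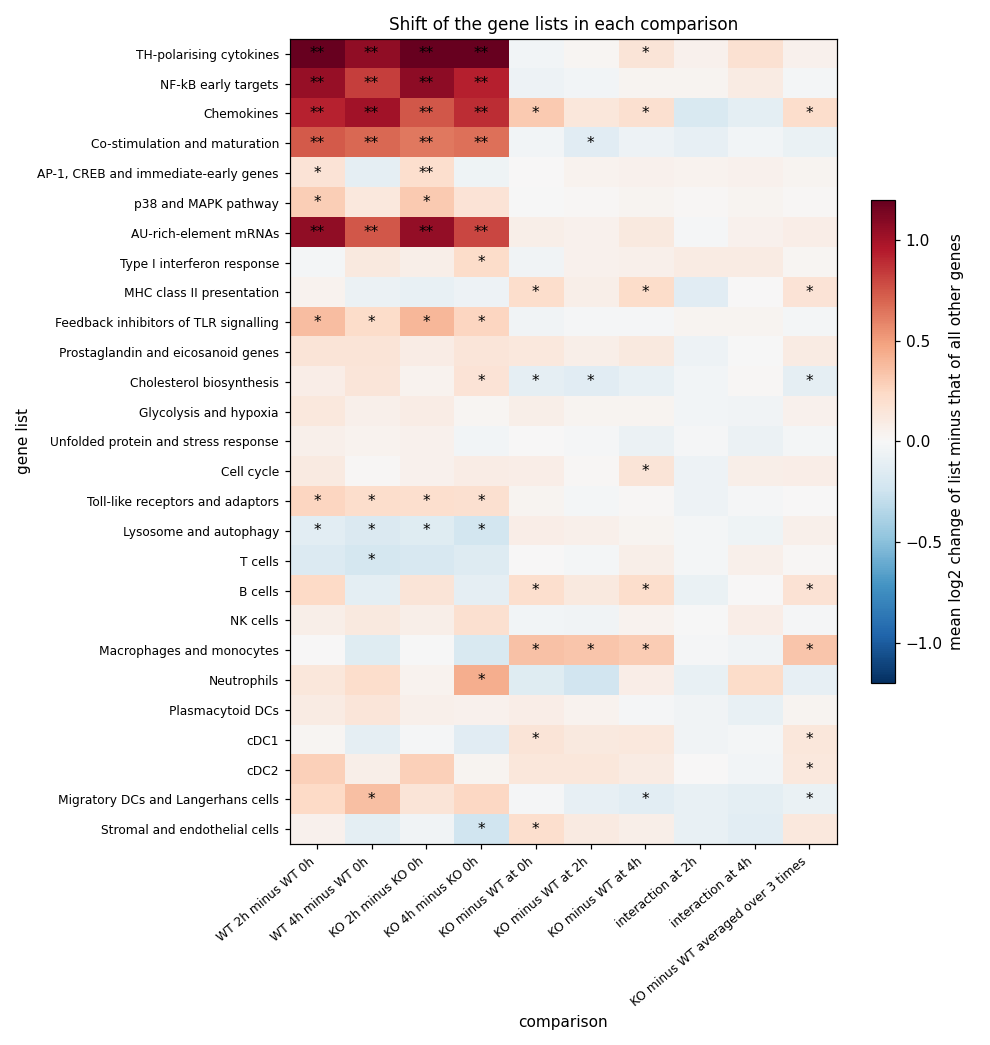
Mean log2 change of each gene list minus that of all other genes, for each comparison (columns) and list (lines of the grid), red above 0 and blue below. One asterisk marks an adjusted p below 0.05 in the preset-correlation test, and a pair of asterisks a call that also holds with an estimated correlation, which all genotype and interaction columns lack.

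Before stimulation single genes already differed between KO and WT arrays, some of them macrophage-associated or chemokine genes. Marco, a scavenger receptor of macrophages, was 2.63-fold higher in KO arrays (1.40 ± 0.15 (SE), adjusted p = 6.1e-05, log2). Lyz2, the myeloid lysozyme, was higher by 0.96 ± 0.08 (adjusted p = 1.1e-05) and the complement gene C1qa by 0.97. The CCR2 ligands Ccl12 (1.64), Ccl7 (1.27) and Ccl2 (1.00) and the related Ccl8 (1.17) were higher too, as were Dcpp1 (2.57), Col27a1 (1.34) and cyclin D1, Ccnd1 (0.97). Among the genes lower in KO arrays were the intracellular serpin Serpinb9b (-1.84 ± 0.09, adjusted p = 1.9e-08), Tex14 (-1.84), Myom1 (-1.45) and Rnf152 (-1.03). Prdm11 (group means 5.63 in KO and 4.41 in WT arrays) was also among the 6 highest called, and lay below the filter level in WT arrays. Etfbkmt (-1.10) and Calm4 (5.16 in KO and 6.16 in WT arrays) were among the 6 lowest. The calls of Prdm11, Etfbkmt and Calm4 were lost without some single arrays. Malt1, the paracaspase of NF-kB signalling, stood at -0.86, and Dusp1, the phosphatase that inactivates p38 and JNK, at -0.48 ± 0.07 (adjusted p = 5.9e-04).

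The cytokine genes Il6 (0.19 ± 0.06, adjusted p = 0.11), Il23a (-0.15), Il12b (-0.34) and Il12a (0.02) did not pass between genotypes at 0 h. Ebi3 was higher by 0.65. Il33 was higher (0.52), a call lost without KO 0 h A or either WT 0 h array (adjusted p up to 0.16). Il1b was lower (-0.46), a call lost without KO 0 h B (adjusted p up to 0.067). Il17a was lower (-0.71), a call lost without KO 0 h A or either WT 0 h array (adjusted p up to 0.18). All 4 of these calls were lost on the deposited scale, and those of Il33, Il1b and Il17a also with eBayes without trend. The cytokine list as a whole had 2 higher and 2 lower of 17 (3 higher and 4 lower adjusted over the list alone; adjusted p = 0.98). Macrophage and monocyte markers were higher in 10 of 18 cases and lower in none (11 higher and 1 lower adjusted over the list alone), with a median of 0.42 (adjusted p = 8.8e-06, but adjusted p = 0.12 with an estimated correlation). Beside that shift, chemokines were higher in 9 of 24 cases (10 higher and 1 lower adjusted over the list alone; adjusted p = 8.9e-04, but adjusted p = 0.12 with an estimated correlation). MHC class II genes were higher in 5 of 18 (7 higher and 0 lower adjusted over the list alone; adjusted p = 0.0027, but adjusted p = 0.36 with an estimated correlation), with H2-Ab1 at 0.51 and H2-Eb1 at 0.34. H2-Ab1 lost its call without KO 0 h B or WT 0 h B (adjusted p up to 0.091), and H2-Eb1 without KO 0 h A (adjusted p up to 0.063). B cell markers were higher in 3 of 16 cases (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.0034, but adjusted p = 0.12 with an estimated correlation), and none of these 3 lists had a lower call among all genes tested. Stromal and endothelial markers were higher in 2 of 17 cases (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.020, but adjusted p = 0.22 with an estimated correlation), with Pdpn at 0.82. Of 14 cDC1 markers 1 was higher (3 higher and 0 lower adjusted over the list alone; adjusted p = 0.042, but adjusted p = 0.22 with an estimated correlation), Batf3 at 0.57. Of 20 cholesterol genes 1 was lower (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.022, but adjusted p = 0.27 with an estimated correlation), Idi1 at -0.44. The stromal call was lost without KO 0 h B or WT 0 h A (adjusted p up to 0.14). The cDC1 call was lost without either KO 0 h array, KO 4 h B, WT 0 h B, either WT 2 h array or WT 4 h A (adjusted p up to 0.13). The cholesterol call was lost without KO 0 h A, KO 4 h A, WT 0 h A, WT 2 h A or either WT 4 h array (adjusted p up to 0.32), and it and the cDC1 call were lost with either other scaling.

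At 0 h 249 genes were higher and 173 lower in KO arrays, 18 and 5 of them at least 2-fold. The total of 422 became 232 without KO 0 h A, 218 without KO 0 h B, 192 without WT 0 h B, and 32 of 62 named calls were lost without at least 1 array. The deposited values gave 10 higher and 21 lower with a median shift of -0.09 and lost 47 of the named calls, and eBayes without trend left 116 genes.

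**Figure D4:**
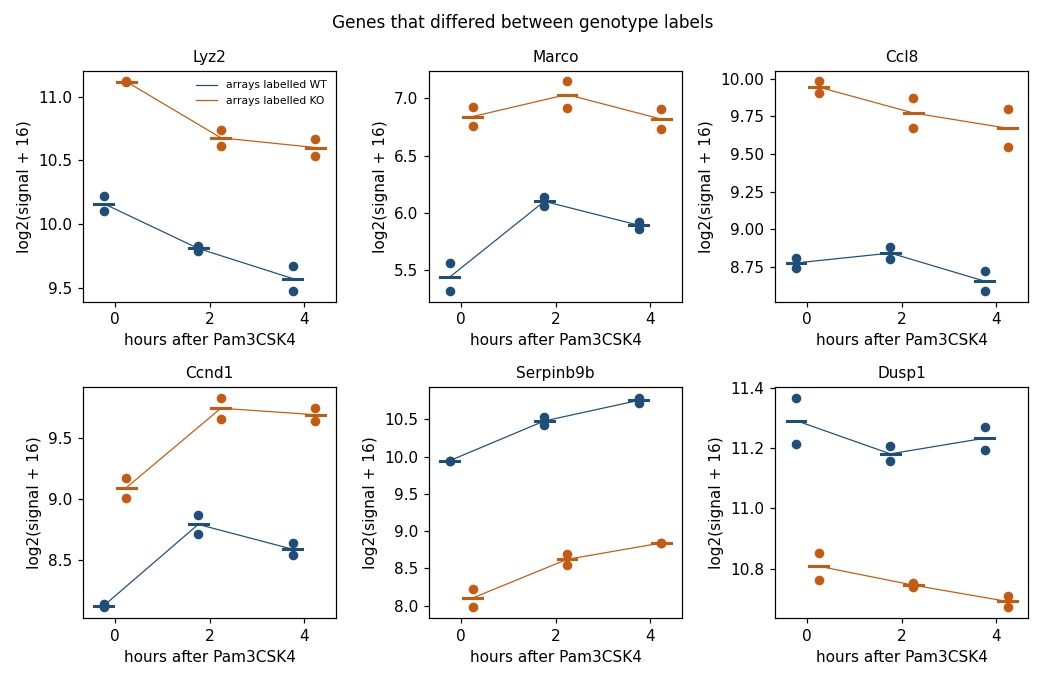
Genes that differed between genotype labels, by time after Pam3CSK4 in log2(signal + 16), with WT arrays in blue and KO arrays in orange. Points are single arrays and bars are means of 2 arrays. Lyz2, Marco, Ccl8 and Ccnd1 lay above WT and Serpinb9b and Dusp1 below it on every KO array of each time, for example Serpinb9b at 8.10 against 9.95 at 0 h.

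At 2 h several of the genes named at 0 h again differed between genotypes. Dcpp1 (1.88 ± 0.27, adjusted p = 0.0014), Ccl12 (1.47), lipoprotein lipase, Lpl (1.08), Ccnd1 (0.96), Ccl8 (0.93), Marco (0.93) and Lyz2 (0.87 ± 0.08, adjusted p = 5.0e-05) were higher in KO arrays. Serpinb9b (-1.86 ± 0.09 (SE), adjusted p = 1.7e-08), Myom1 (-1.76), the integrin chain Itgb8 (-1.67), Dnah2 (-1.55) and Tex14 (-1.41) were lower. Stx11 (-0.66) and the cystine transporter Slc7a11 (-0.56) were lower as well. Also among the 6 highest called were Dlk2 (group means 5.80 in KO and 4.48 in WT arrays), Des (6.16 and 4.85) and Tbkbp1 (6.11 and 5.02). Zfp819 (4.48 in KO and 6.08 in WT arrays) was among the 6 lowest. Dlk2 in WT arrays and Zfp819 in KO arrays lay below the filter level. Dusp1 stood at -0.43 and the IL-2 receptor chain Il2ra at -0.81, calls lost without WT 2 h B (adjusted p up to 0.0503) and without KO 2 h B (adjusted p up to 0.061) respectively.

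No difference passed at 2 h for Il6 (-0.12 ± 0.06, adjusted p = 0.36), Il23a (-0.19 ± 0.17), Il12b (0.10), Il12a (-0.02), Il1a (0.48) or Tnf (0.38). Ebi3 was the 1 cytokine of 17 called (0.27, adjusted p = 0.0475), and it turned to -0.05 on the deposited scale. Its call was also lost without either KO 2 h array, either KO 4 h array, either WT 2 h array or either WT 4 h array (adjusted p up to 0.25). The list had 4 higher and 1 lower adjusted over the list alone and an adjusted p of 0.90. Macrophage markers were higher in 8 of 18 cases and lower in none (9 higher and 0 lower adjusted over the list alone), with a median of 0.38 (adjusted p = 3.2e-06, but adjusted p = 0.18 with an estimated correlation). Co-stimulation genes were lower in 4 of 27 cases and higher in 1 (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.029, but adjusted p = 0.31 with an estimated correlation), among them the PD-1 ligand Pdcd1lg2 (-0.42) and the homing receptor Ccr7 (-0.27). Cholesterol genes were lower in 2 of 20 cases (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.016, but adjusted p = 0.31 with an estimated correlation), Idi1 and Cyp51 (-0.41 and -0.38). The co-stimulation call was lost without KO 0 h B, KO 2 h B or either WT 2 h array (adjusted p up to 0.21). The cholesterol call was lost without KO 2 h A or WT 2 h B (adjusted p up to 0.28). Pdcd1lg2 lost its call without either KO 2 h array or either WT 2 h array (adjusted p up to 0.11), and Ccr7 without either KO 2 h array or either WT 2 h array (adjusted p up to 0.14). Idi1 lost its call without KO 2 h A or WT 2 h B (adjusted p up to 0.093), and Cyp51 without either KO 2 h array or either WT 2 h array (adjusted p up to 0.17).

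The 2 h counts were 129 higher and 165 lower, with 12 and 12 at least 2-fold. The total of 294 became 147 without KO 2 h A, 90 without KO 2 h B, 155 without WT 2 h A, 67 without WT 2 h B, 33 of 48 named calls being lost without at least 1 array. The deposited scale gave 5 higher and 61 lower with a median shift of -0.15, and eBayes without trend 71 genes.

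At 4 h Ccl12 (1.60 ± 0.19 (SE), adjusted p = 3.2e-04), Ccnd1 (1.11), Lyz2 (1.03), Ccl8 (1.02), Ccl7 (0.93), Marco (0.92) and Ccl2 (0.84) were higher in KO arrays. Map3k5, the kinase ASK1 that acts upstream of p38 and JNK, was higher by 0.86 ± 0.13 (adjusted p = 0.0014). Lower in KO arrays were Serpinb9b (-1.91), the chloride channel Clcn5 (-1.40, lost with the mean of all probe sets and without suffixed probe sets), Tex14 (-1.36) and the fatty acid oxidation enzyme Acadm (2.29-fold lower, adjusted p = 5.4e-07). Pdcd1lg2 (-0.64), Ddit4 (-0.65), Slc7a11 (-0.61) and Dusp1 (-0.54 ± 0.07) were lower. Also among the 6 highest called were Dcpp1 (1.62) and Sema3f (group means 6.21 in KO and 4.73 in WT arrays). Fcna (5.52 and 4.25), Hsd11b2 (5.47 and 4.26) and Emx1 (5.54 and 4.41) completed them with Ccl12. Lce1h (4.45 and 5.93) and Myom1 (-1.17) were among the 6 lowest. Sema3f, Fcna, Hsd11b2 and Emx1 in WT arrays and Lce1h and Myom1 in KO arrays lay below the filter level. Zfp36, which encodes the AU-rich-element binding protein tristetraprolin, was at -0.37, a call lost without KO 4 h B or WT 4 h A (adjusted p up to 0.17).

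Tnf (0.68 ± 0.13, adjusted p = 0.0099), Il1a (0.63 ± 0.15, adjusted p = 0.031) and Ebi3 (0.27, adjusted p = 0.042) were higher in KO arrays at 4 h. The Tnf call was lost without either KO 4 h array or either WT 4 h array (adjusted p up to 0.11). The Il1a call was lost without either KO 4 h array or WT 4 h B (adjusted p up to 0.34). The Ebi3 call was lost without either KO 2 h array, either KO 4 h array, either WT 2 h array or either WT 4 h array (adjusted p up to 0.27). Each was lost on the deposited scale and with eBayes without trend. Il6 (0.06 ± 0.06), Il23a (0.30 ± 0.17), Il12b (0.24), Il12a (0.18) and Il17a (0.18) did not pass. The cytokine list had 3 of 17 higher (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.029, but adjusted p = 0.20 with an estimated correlation). Macrophage markers were higher in 7 of 18 cases (8 higher and 1 lower adjusted over the list alone; median 0.26, adjusted p = 3.1e-05, but adjusted p = 0.17 with an estimated correlation). MHC class II genes were higher in 5 of 18 cases (6 higher and 0 lower adjusted over the list alone; adjusted p = 8.2e-04, but adjusted p = 0.27 with an estimated correlation). B cell markers were higher in 1 of 16 (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.0091, but adjusted p = 0.17 with an estimated correlation). Cell cycle genes were higher in 2 of 34 (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.019, but adjusted p = 0.22 with an estimated correlation). Chemokines were higher in 6 of 24 with 1 lower (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.0490, but adjusted p = 0.27 with an estimated correlation). Migratory dendritic cell markers were lower in 4 of 18 cases (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.022, but adjusted p = 0.20 with an estimated correlation). The cytokine list lost its call without KO 4 h A or either WT 4 h array (adjusted p up to 0.32), and the MHC list without KO 4 h A (adjusted p up to 0.0508). The B cell list lost its call without KO 4 h A or WT 4 h A (adjusted p up to 0.15), and the cell cycle list without KO 4 h B or WT 4 h B (adjusted p up to 0.082). The chemokine list lost its call without either KO 0 h array, either KO 2 h array, either KO 4 h array, either WT 0 h array or either WT 4 h array (adjusted p up to 0.11). The migratory list lost its call without either KO 4 h array or WT 4 h B (adjusted p up to 0.15). The cytokine call was also lost on the deposited scale and the migratory call with either other scaling.

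At this time 145 genes were higher and 161 lower, 10 and 14 at least 2-fold. The total of 306 became 154 without KO 4 h A, 102 without KO 4 h B, 127 without WT 4 h A, 103 without WT 4 h B, and 38 of 56 named calls were lost without at least 1 array. Deposited values gave 5 higher and 38 lower with a median shift of -0.14, and eBayes without trend gave 85 genes.

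Averaged over the 3 times, with 6 arrays against 6, the genotypes differed in 794 genes higher and 548 lower in KO arrays, 7 and 7 of them at least 2-fold. Highest were Dcpp1 (2.02), Ccl12 (1.57), Marco (1.08), Ccl8 (1.04) and Lpl (1.03) and the myelin gene Pmp22 (1.03), and Lyz2 (0.95 ± 0.05, adjusted p = 5.9e-09), Ccnd1 (1.01), Ccl7 (0.96), Ccl2 (0.82) and C1qa (0.75) followed. Lowest were Serpinb9b (-1.87 ± 0.05 (SE), adjusted p = 4.3e-12), Tex14 (-1.54), Myom1 (-1.46) and Itgb8 (-1.23), the calmodulin-like Calm4 (-1.07) and Etfbkmt (-1.04). Dusp1 was lower by a log2 difference of -0.49 ± 0.04 (adjusted p = 7.6e-07), Zfp36 of -0.28, Dusp5 of -0.32 and c-Rel, Rel, of -0.43. Dusp1 lies among the 100 tested genes nearest Mapk14, so for it a flanking segment from another strain cannot be told apart from p38α loss. Il2ra (-0.75), Arc (-0.80), Slc7a11 (-0.61), Stx11 (-0.51), Idi1 (-0.42) and Pdcd1lg2 (-0.40) were lower too.

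Il6 (0.04 ± 0.03, adjusted p = 0.51), Il23a (-0.01 ± 0.10, adjusted p = 0.96), Il12b (-0.0003 ± 0.11), Il12a (0.06) and Il10 (-0.05) did not pass in the averaged difference. Among the 17 cytokines 4 were higher and 2 lower (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.55): Il1a (0.48), Il33 (0.44), Tnf (0.42) and Ebi3 (0.40) higher, Il1b (-0.20) and Il17a (-0.36) lower. The 4 higher calls were lost on the deposited scale. Il1b lost its call without KO 2 h B or WT 2 h A (adjusted p up to 0.0512), and Il17a without KO 0 h A or KO 4 h B (adjusted p up to 0.058). Macrophage markers gave 10 higher and 1 lower of 18 (11 higher and 1 lower adjusted over the list alone), with a median of 0.35 (adjusted p = 2.8e-06, but adjusted p = 0.093 with an estimated correlation). In the same arrays MHC class II genes were higher in 7 of 18 cases (8 higher and 0 lower adjusted over the list alone; adjusted p = 0.0025, but adjusted p = 0.26 with an estimated correlation), for instance H2-DMa (0.53) and H2-Ab1 (0.46). B cell markers were higher in 4 of 16 (6 higher and 0 lower adjusted over the list alone; adjusted p = 0.0022, but adjusted p = 0.093 with an estimated correlation), for instance Bank1 (0.50). Chemokines were higher in 9 of 24 with 1 lower (9 higher and 3 lower adjusted over the list alone; adjusted p = 0.014, but adjusted p = 0.18 with an estimated correlation). Cholesterol genes were lower in 2 of 20 (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.0027, but adjusted p = 0.18 with an estimated correlation). Markers of cDC1 were higher in 5 of 14 cases (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.034, but adjusted p = 0.18 with an estimated correlation). Markers of cDC2 gave 4 higher and 1 lower of 15 (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.034, but adjusted p = 0.18 with an estimated correlation). Migratory markers gave 6 lower and 4 higher of 18 (4 higher and 8 lower adjusted over the list alone; adjusted p = 0.039, but adjusted p = 0.18 with an estimated correlation), with the list down. The cDC1 list lost its call without KO 0 h B, KO 2 h B, either KO 4 h array, WT 0 h B or WT 2 h A (adjusted p up to 0.094). The cDC2 list lost its call without KO 0 h B, KO 4 h A or WT 0 h A (adjusted p up to 0.077) and with trimmed-mean scaling. The migratory list lost its call without KO 0 h B, KO 2 h B, KO 4 h B, WT 0 h A, WT 2 h B or WT 4 h B (adjusted p up to 0.096) and with either other scaling.

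Genotype differences recurred across the times: 52 genes were higher and 76 lower in KO arrays at all 3. Between 0 and 2 h 72 genes were higher and 100 lower at both, where independent lists would share 2.51 and 2.23. The pairs 0 and 4 h (82 and 89, against 2.82 and 2.18) and 2 and 4 h (62 and 93, against 1.46 and 2.08) were alike. No arrays are shared between times, but the labels do not say that the times came from separate cell preparations. The recurrence may therefore not be independent. On the deposited scale the averaged split was 49 higher and 488 lower, with a median shift of -0.12, and 40 of 82 named calls were lost. With eBayes without trend 881 genes were called, in place of 1342.

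Whether the response itself differed between genotypes was tested by the difference of the 2 responses. At 2 h Ccl6, a myeloid chemokine, rose by 1.87 in WT and 0.53 in KO arrays, a difference of -1.34 ± 0.17 (SE), adjusted p = 0.0046. Dnah2, whose other probe set above the filter went the other way, fell more in KO arrays (-0.68 in WT, -2.10 in KO, difference -1.42, adjusted p = 4.7e-04). The collagen gene Col27a1 and Procr, the endothelial protein C receptor, rose less in KO arrays, with differences of -1.001 and -0.77. Col27a1 lost its call without KO 0 h B, either KO 2 h array or either WT 2 h array (adjusted p up to 0.14), and Procr without KO 0 h B, KO 2 h A or WT 2 h A (adjusted p up to 0.13). At 4 h Ccl6 again rose less (-1.33 ± 0.17 (SE), adjusted p = 0.0050), a call lost without KO 4 h A or WT 4 h A (adjusted p up to 0.060). The sphingosine kinase Sphk1 also rose less (-1.09), a call lost without either KO 0 h array, KO 4 h A, WT 0 h B or either WT 4 h array (adjusted p up to 0.14). Malt1 rose in KO arrays by 0.82 against a change of -0.17 in WT arrays (0.99 ± 0.12), a call lost without KO 4 h A or WT 4 h A (adjusted p up to 0.060). The chromatin gene Chrac1 (0.90), Col27a1 (-0.89) and the tetraspanin Cd81 (-0.63) had adjusted p = 0.040 each. They lost their calls without 10, 12 and 11 of the 12 arrays in turn (adjusted p up to 0.21, 0.25 and 0.25). For some of these genes the difference lay largely in a gap at 0 h that narrowed. Malt1 stood at 9.01 in KO and 9.88 in WT arrays at 0 h and at 9.84 and 9.71 at 4 h. Col27a1 stood at 7.12 and 5.78 at 0 h and stayed higher in KO arrays at 4 h (8.60 and 8.15). Cd81 was higher in KO arrays by 0.95 at 0 h and by 0.32 at 4 h. Dnah2 differed little at 0 h (10.89 in KO and 11.02 in WT arrays). Il6 (-0.32 ± 0.08 at 2 h, adjusted p = 0.45, -0.13 at 4 h), Il23a (-0.03 and 0.45), Il12b (0.43 and 0.58), Ebi3 (-0.38 and -0.38) and Il17a (0.16 and 0.89) did not pass. In simulated data this test at 2 h found 8.96% of changes of 0.5, so genes that did not pass may still differ.

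These were all the calls: limma gave 4 genes at 2 h, with 754 at an unadjusted p under 0.05, and 6 at 4 h, with 775. Counts at 2 h were 2 without KO 2 h A or without WT 2 h A, 7 without KO 4 h B and 8 without WT 0 h A. At 4 h they were 0 without KO 4 h A or without WT 4 h A, 2 without WT 0 h B or without WT 4 h B, and 3 without KO 0 h A or without KO 0 h B. The split was 1 higher and 2 lower at 2 h and 0 and 2 at 4 h on the deposited scale, and no gene passed at either time with eBayes without trend or with the mean of all probe sets. The 2 comparisons share the 0 h arrays: their differences correlated across genes with r = 0.419 (covariance 0.0300), against 0.499 (covariance 0.0310) in 50 simulations without any effect. No list passed. Chemokines, which had 6 lower adjusted over the list alone at 2 h, came nearest with the type I interferon list (adjusted p = 0.059 and 0.059). The chemokine list passed with trimmed-mean scaling (0.029) and on the deposited scale (0.0047). With quantile normalization its adjusted p was 0.87 at an estimated correlation, which was not fitted with the other scalings.

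As a set, the genes that rose at least 2-fold from 0 h over both genotypes rose slightly less in KO arrays. At 2 h 205 genes had a median change of 1.44 in WT and 1.32 in KO arrays and a median difference of -0.13, with 150 of them below 0 (73.2%, against 51.9% of other genes). Camera gave p = 1.9e-08, or p = 0.018 with an estimated correlation. Before stimulation these genes stood higher in KO arrays by a median of 0.14, 31 called higher and 8 lower, and at 2 h they stood at -0.03, 7 higher and 13 lower. At 4 h 147 genes had a median difference of -0.054 (p = 0.018, but p = 0.26 with an estimated correlation). The mean of this set minus other genes, -0.055, was no longer called without KO 0 h A (-0.013), without KO 4 h B (-0.048), on the deposited scale (-0.058) or with a pseudocount of 1 (-0.037).

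**Figure D5:**
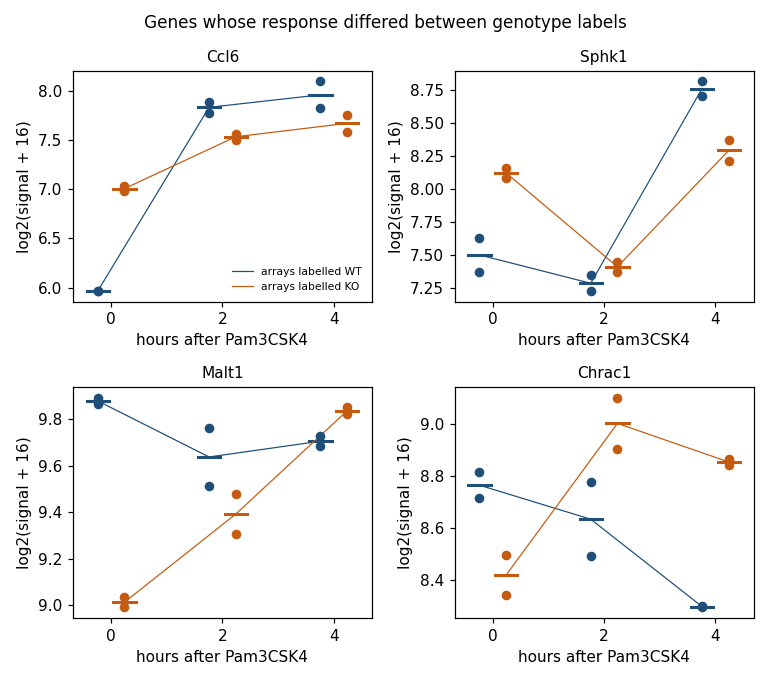
Genes whose change after Pam3CSK4 differed between genotype labels, by time in log2(signal + 16), with WT arrays in blue and KO arrays in orange. Points are single arrays and bars are means of 2 arrays. Ccl6 stood at 5.96 in WT and 7.01 in KO arrays at 0 h and at 7.83 and 7.53 at 2 h.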

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

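The tests of the macrophage marker and Mapk14 patterns were chosen after their results were seen; those of the recurring genotype differences and of the relabelled arrays were chosen before. Of 12792 genes, those called in the test of the difference between genotype responses are listed here with their changes in each genotype. At 2 h these were Dnah2 (-1.42, from -0.68 in WT and -2.10 in KO arrays), Ccl6 (-1.34, from 1.87 and 0.53), Col27a1 (-1.001, from 2.28 and 1.28) and Procr (-0.77, from 2.23 and 1.46). At 4 h they were Malt1 (0.99, from -0.17 and 0.82), Chrac1 (0.90, from -0.46 and 0.43), Ccl6 (-1.33, from 1.99 and 0.66), Sphk1 (-1.09, from 1.26 and 0.17), Col27a1 (-0.89, from 2.37 and 1.48) and Cd81 (-0.63, from 1.84 and 1.21). The ligand-induced genes as a set differed between genotypes by a median of -0.13 at 2 h and -0.054 at 4 h, the latter lost with an estimated correlation (p = 0.26).

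Macrophage and monocyte markers were higher in arrays labelled KO at all 3 times, calls lost with an estimated correlation (adjusted p = 0.12, 0.18 and 0.17), and scaling is argued against as their source by the highest adjusted p over the 3 scalings at the preset correlation, 3.74e-06. A lower share of dendritic cells would raise markers of every other cell type alike. The macrophage list lay above T cell, NK cell and neutrophil markers by 0.350 ± 0.098 (SE) and above these with B cell and stromal markers by 0.272 ± 0.097. It was not clearly above B cell markers alone (0.151 ± 0.10) or stromal markers alone (0.201 ± 0.11). These errors were taken over genes as if independent, not over arrays, and are too small where genes of a list vary together. They therefore cannot decide against a lower share of dendritic cells. A further list of 40 macrophage-abundant genes, 36 of them measured and 0 in another fixed list, had a median of 0.22, with 18 called higher and 1 lower. That median lay at percentile 100 of 10000 random lists matched on mean level (central 95% from -0.03 to 0.07). Random lists take genes as independent, so the percentile overstates the evidence where macrophage genes vary together between arrays. Among abundant members of the further list Apoe differed by 0.71 (mean level 8.88), Lgals3 by 0.25 (12.21), Psap by 0.14 (11.91), Grn by 0.09 (11.41) and Tyrobp by 0.01 (11.30). Of the 36, 35 were above the filter in WT arrays, and dendritic cells express many of them. A candidate explanation that stays open is therefore more macrophages or monocytes in the KO preparations, for which no sort or gate was given in the sources used here, and a change of these genes within dendritic cells that lack p38α also stays open and was not tested.

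In all, 128 genes were called in one direction between genotypes at each of the 3 times. Among the 100 tested genes nearest Mapk14 lay 1 of them, Dusp1, where 1.00 was expected (Fisher's exact test, two-sided, p = 1.00). These nearest genes were therefore not enriched. Whether a chromosome segment from another strain was the main source cannot be decided by this. A window of 100 genes could hardly hold most of 128, and longer segments were not tested. For Dusp1 itself a segment from another strain cannot be told apart from an effect of p38α loss. Sequence variants under single probe sets are argued against for the 67 of the 128 genes that had another probe set above the filter. Of 121 such probe sets 95.04% differed in the same direction, against 55.8% for genes not called. The exact 95% interval, 89.5 to 98.2%, takes probe sets of one gene as independent. The remaining genes had no other probe set above the filter and were not tested. Strain variants clustered elsewhere in the genome cannot be told apart from their absence, because 15 close pairs of these genes against a median of 12 in random draws (permutation p = 0.264) decides neither way. A lasting effect of p38α loss on these genes may underlie the pattern, as may a difference in cell makeup, and these stay open.

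The Mapk14 signal was not lower in arrays labelled KO: 0 of 6 probe sets lay lower at adjusted p under 0.05 in the averaged difference, by limma, but only 3 of them were above the expression filter. The brightest differed by 0.31, higher in KO. Probe sets outside the deleted part could give this, and exchanged genotype labels cannot be told apart from it, since the position of the deletion relative to the probe sets was not given in the sources used here.

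For the averaged genotype difference, 100 splits that relabel single arrays within each time were drawn, out of 108 possible: 1 gave as many called genes, the real one with 1342, and the highest of the others gave 90. These splits treat the 2 arrays of a group as separate samples, which the labels do not state, and splits of whole groups are too few for a share under 0.05.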

How the results depend on the processing

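Trimmed-mean scaling was chosen after seeing the data, and the other alternatives before. Under all of them 16510 values of named genes kept their side of the threshold, 1137 lost a call, 49 gained one and 10 reversed. Of list tests 6439 kept their side, 185 lost and 68 gained a call. Values called in neither setting counted as kept even where their sign turned. With trimmed-mean scaling, a pseudocount of 64, the 60th percentile filter or the replicate block, each total of called genes stayed within 1.5 times its main value. On the deposited scale 832 genes were called in WT arrays at 4 h, 853 in KO arrays at 4 h, 31, 66 and 43 between genotypes at 0, 2 and 4 h, 537 in the averaged difference and 2 in the difference of responses at 4 h. There Spib in WT arrays at 2 h (-0.064), Il1b (-0.069), Stard4 (-0.15), Ly6d (-0.043) and Irf8 (-0.049) in KO arrays at 2 h, Ebi3 between genotypes at 2 h (-0.051) and Irf8 in the averaged difference (-0.048) reversed, on a scale that shifts the median of all genes downward in each of these comparisons. The mean of the ligand-induced set minus other genes at 4 h was -0.058 there, -0.037 with a pseudocount of 1 and -0.055 with an estimated correlation, no longer called in any of these. EBayes without trend called 116, 71 and 85 genes between genotypes at 0, 2 and 4 h, 881 averaged and 0 and 0 in the differences of responses at 2 and 4 h. The mean of all probe sets gave 198 between genotypes at 4 h and 0 and 0 in the differences of responses, and turned Mcm2 in the averaged difference to -0.027. Probe sets without the suffixes turned Laptm5 at 4 h to 0.81 in WT and 0.80 in KO arrays. With only the groups compared, which leaves fewer arrays to estimate the spread, 229 and 193 genes were called between genotypes at 0 and 4 h; the averaged difference uses every group and has no such value. No filter left 3 genes in the difference of responses at 4 h. At adjusted p under 0.1 the calls were 522 and 478 between genotypes at 2 and 4 h and 9 in the difference of responses at 2 h, by the looser threshold. Requiring a log2 change of at least 1 left 319 and 265 genes in WT arrays and 295 and 258 in KO arrays at 2 and 4 h, 23, 24 and 24 between genotypes at 0, 2 and 4 h, 14 averaged and 2 in the difference of responses at 4 h. Leaving out 1 array, where the lone remaining array is assumed to vary like the other groups, gave 1721 to 2521 called genes in WT arrays at 2 h, 1585 to 2325 at 4 h, 1593 to 2489 in KO arrays at 2 h (lowest without KO 0 h A), 1644 to 2336 at 4 h, and 1013 to 1312 averaged. Between genotypes it gave 192 to 403 (lowest without WT 0 h B), 67 to 307 (lowest without WT 2 h B) and 102 to 318 (lowest without KO 4 h B) at 0, 2 and 4 h. The differences of responses gave 2 to 8 genes at 2 h and 0 to 5 at 4 h, and the ligand-induced set gave -0.17 to -0.11 at 2 h and -0.077 to -0.013 at 4 h, the latter without KO 0 h A. Unless stated, the cause was not tested.

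Arrays with the same letter did not deviate together: over 15 pairs of groups the correlation of deviations ran from -0.0422 to 0.105, with 1 above 0.1, so the letters give no pairing. With the letter as a replicate block 2638, 2462, 2611 and 2425 genes responded in WT and KO arrays at 2 and 4 h, 464, 315 and 345 differed between genotypes at 0, 2 and 4 h, 1418 averaged, and 6 and 6 in the responses. Genes near the filter level of 4.73 have little signal over background, and their changes are understated.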

Other observations

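Values here were chosen for mention after the data were seen. The lists of this paragraph did not pass in the comparisons named with them. Prostaglandin and eicosanoid genes gave 2 higher and 1 lower of 15 (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.64) in WT arrays at 2 h and adjusted p = 0.086 in the averaged genotype difference, although Ptgs2 of that list rose by 2.46 in WT arrays. Glycolysis and hypoxia genes gave 7 higher and 2 lower of 27 (7 higher and 4 lower adjusted over the list alone; adjusted p = 0.38) in the same comparison. Unfolded protein and stress response genes gave 8 higher and 4 lower of 33 (8 higher and 8 lower adjusted over the list alone; adjusted p = 0.78) there. In the averaged genotype difference, NK cell markers gave 1 higher and 1 lower of 14 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.93). Plasmacytoid dendritic cell markers gave 2 higher and 2 lower of 14 (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.95). T cell markers gave 2 higher and 2 lower of 16 (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.73) and neutrophil markers 0 higher and 0 lower of 10 (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.21), and 1 erythroid gene was measured and not called.

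Mki67, a nuclear protein of dividing cells, rose by 3.99 in WT and 3.63 in KO arrays at 2 h and still stood 2.62 and 2.09 above 0 h at 4 h. The cell cycle list did not pass in WT arrays at 2 h, with 6 higher and 5 lower of 34 (6 higher and 5 lower adjusted over the list alone; adjusted p = 0.75). Ifng, an interferon made chiefly by T and NK cells, rose in both genotypes at 4 h. At that time T cell markers gave 0 higher and 2 lower of 16 (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.16) in KO arrays. In WT arrays they gave 0 higher and 4 lower of 16 (0 higher and 5 lower adjusted over the list alone; adjusted p = 0.037), a call lost at adjusted p = 0.15 with an estimated correlation. It was also lost without either WT 0 h array or WT 4 h A (adjusted p up to 0.095) and on the deposited scale. NK cell markers gave 4 higher and 2 lower of 14 (5 higher and 2 lower adjusted over the list alone; adjusted p = 0.54) in WT arrays. In KO arrays they gave 4 higher and 1 lower of 14 (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.29). Changes of these lists from 0 h do not show whether T or NK cells were in the cultures, and the source of Ifng was not tested. At 0 h the NK list members Klrd1 (9.32 in WT and 9.27 in KO arrays) and Gzmb (9.62 and 9.91) already stood far above the filter level of 4.73. Tbx21 of that list stood lower (6.04 and 6.11). S100a8 rose by 1.66 in WT and 1.67 in KO arrays at 4 h.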
